A study of Arabidopsis thaliana with 4 samples.

How the data were processed

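Small RNA libraries from siliques of 4 Arabidopsis thaliana crosses, 5 days after fertilization, were analysed, with 1 library per cross (ColxCol, LerxLer, ColxLer and LerxCol). Per the labels, RNA was extracted by a standard method. The authors deposited, for each library, a list of read sequences with 1 read per entry and no names, counts or positions. Sequencing, adapter trimming, filters, genome build and aligner are not given in the sources used here. The deposited sequences were 15 to 27 nt long. No transposon annotation was used here. Transposon remnants annotated as pseudogenes are counted there. Other transposon sequence falls in the class of its place, which is intergenic where no gene is annotated.

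The deposited lists still held adapter sequence. Reads that shared 12 nt with the 5' adapter (26 nt) or the 3' adapter (21 nt) of the small RNA kit were removed, and so were reads without a perfect genome match that came within 4 mismatches of an adapter. This step was chosen after the data were seen. It removed 24.8% of reads in ColxCol, 26.1% in LerxLer, 25.9% in ColxLer and 16.0% in LerxCol. Reads of 18 to 27 nt were kept, and their number per library is the total for all levels in RPM (reads per 1000000), structural RNA included.

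Each distinct sequence was matched to the TAIR10.1 assembly with its RefSeq annotation by an exact hash search of both strands (Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Numba 0.67.0). All perfect places were kept and reads with several were split equally among them. Reads with no perfect place were searched with 1 mismatch, which entered only the allele analysis and 1 alternative. A perfect match was found for 71.5% of reads in ColxCol, 53.0% in LerxLer, 71.3% in ColxLer and 56.2% in LerxCol. No match within 1 mismatch was found for 10.5%, 22.7%, 10.7% and 20.9%. A Col reference therefore undercounts diverged Ler sequence in LerxLer and LerxCol. Each place was given 1 class in the order organelle, structural RNA, miRNA gene, TAS gene, pseudogene, protein-coding gene, other RNA gene and intergenic. The 25S rRNA is not in the annotation, so structural RNA was extended by 4000 nt past each 5.8S rRNA and 300 nt ahead of each rRNA.

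Of miRNAs, 59 mature sequences of 44 families were fixed in lists before the data were examined, and all 59 matched genes of their family. Levels are exact mature sequences in RPM with exact Poisson intervals, and a ratio of 2 libraries has an exact conditional binomial interval. For siRNAs, 24-nt reads outside structural RNA and organelles were summed in 238296 windows of 500 nt by the middle base. A window differed when its log2 ratio, with a pseudocount of 1 RPM, was at least 2 in size (4-fold) and the higher library had at least 10 RPM. A log2 ratio with a pseudocount understates the change of low windows. No p-value was computed. Counting error was simulated in 100 draws from the pooled rates. Folds against 0 reads are given as "at least" a value, taken against a floor of 3 reads per library. They leave out the counting error of the higher count. The slope used 1000 bootstrap draws of windows, and so did the intervals of medians. The slope expected from counting error was simulated in 100 draws, with the rate of each window pooled over a selfed library and the hybrid that begins with the same accession, so the simulation uses the hybrid reads too.

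Allele positions were defined from the selfed libraries alone: at least 10 reads in each, at least 95% with the reference base in ColxCol and at least 95% with the same other base in LerxLer, from reads with a single place. Hybrid reads were then counted by allele, pooled over positions, with exact binomial intervals. For the 5 gene lists (57 entries, all 57 annotated), reads of 20 to 25 nt in the gene and 500 nt on either side were counted. AGL36 stood in both the type I MADS-box and the maternally expressed list. PHE1 stood in both the type I MADS-box and the paternally expressed list. A list's median over members with at least 10 reads was set against 10000 random lists.

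The named miRNAs were the families with at least 100 reads and a 2-fold ratio in either comparison plus the 5 most abundant. Named regions joined touching windows and were the 10 highest and 10 lowest ratios per comparison among windows with at least 50 reads in the higher library, named by the gene they overlap or the nearest within 1000 nt. The reads of a region are counted over its whole length, so some may lie outside the gene that names it. Detected members of the fixed lists could also be named, as miR408 was.

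Alternatives chosen beforehand changed the library total (matched reads outside structural RNA, or miRNA reads), multiple matches, mismatches, window size (1000 nt), minimum (20 RPM), pseudocount (5 RPM), position minimum (20 reads), purity (99%), distinct sequences in place of reads, shifted miRNA ends (2 nt) and the flank of genes. For the scalings the factors were set to a geometric mean of 1. Those added later were a minimum of 50 RPM, totals without the most frequent 18S rRNA sequence, reads of 20 to 25 nt, an 8-fold rule, positions with at least 3 reads, allele reads of 18 to 27 nt, and ratios of a hybrid over a selfed library without the 18S rRNA sequence.

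The matching and allele steps were tested on simulated reads of chromosome 4. Of 22683 distinct error-free sequences, 99.9% were placed at their origin, 280 of 298 simulated positions were found with 0 false ones among the 280, and simulated first-accession shares of 90% and 60% came back as 90.0% and 60.1%. The window rule was tested on counts drawn from the real rates of all 238296 windows, with 200 windows changed 8-fold. For ColxCol over LerxLer it recovered 82.0% of changed windows at 10 to 50 RPM and 97.5% at 50 to 200, and called 9.10% and 0.455% of unchanged windows. For ColxLer over LerxCol it recovered 86.0% and 99.5%, and called 3.00% and 0% of unchanged windows. Figures were drawn with Matplotlib 3.10.9.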

Results

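Small RNAs were sequenced from siliques, the fruits of Arabidopsis thaliana that hold the developing seeds, 5 days after fertilization. The plants belonged to the accessions Columbia (Col) and Landsberg erecta (Ler). There were 4 crosses with 1 library each: the selfed crosses ColxCol and LerxLer, and the reciprocal hybrids ColxLer and LerxCol. By convention the seed parent is written first in a cross, but the labels do not state the order, so the text speaks of the accession written first. The libraries held 264149 reads for ColxCol, 374820 for LerxLer, 382288 for ColxLer and 588518 for LerxCol. After removal of adapter sequence, 186864, 263645, 272951 and 471548 reads of 18 to 27 nt remained in the same order, and levels are given as RPM, reads per 1000000 of these. With 1 library per cross, no difference below has a replicate check, each compares libraries rather than crosses, and the 95% intervals cover counting error only. A count of 0 allows up to 3 reads, which is 16.1 RPM in ColxCol, 11.4 in LerxLer, 11.0 in ColxLer and 6.36 in LerxCol. Folds given as "at least" a value use this floor and leave out the counting error of the higher count.

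Reads of 24 nt, the size class of the siRNAs that direct DNA methylation, were the largest class in all 4 libraries. They made up 52.4% (52.2 to 52.6) of the reads in ColxCol, 61.5% (61.3 to 61.7) in LerxLer, 57.6% (57.4 to 57.8) in ColxLer and 60.3% (60.1 to 60.4) in LerxCol. The intervals are exact binomial. The 21-nt class, which holds most miRNAs and trans-acting siRNAs, took a smaller part, between 9.09% in ColxLer and 9.63% in ColxCol. The 23-nt class also varied between libraries, with 19.7% in ColxCol, 11.0% in LerxLer, 16.7% in ColxLer and 13.6% in LerxCol. Much of that spread lay in 1 sequence of 23 nt from the 18S rRNA (chromosome 2, positions 3706 to 3728 of TAIR10.1), which supplied 7.57% of reads in ColxCol and 0.219% in LerxLer. Among 24-nt reads matched outside structural RNA, 74.2% began with A in ColxCol, 71.2% in LerxLer, 72.3% in ColxLer and 69.2% in LerxCol.

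**Figure D1:**
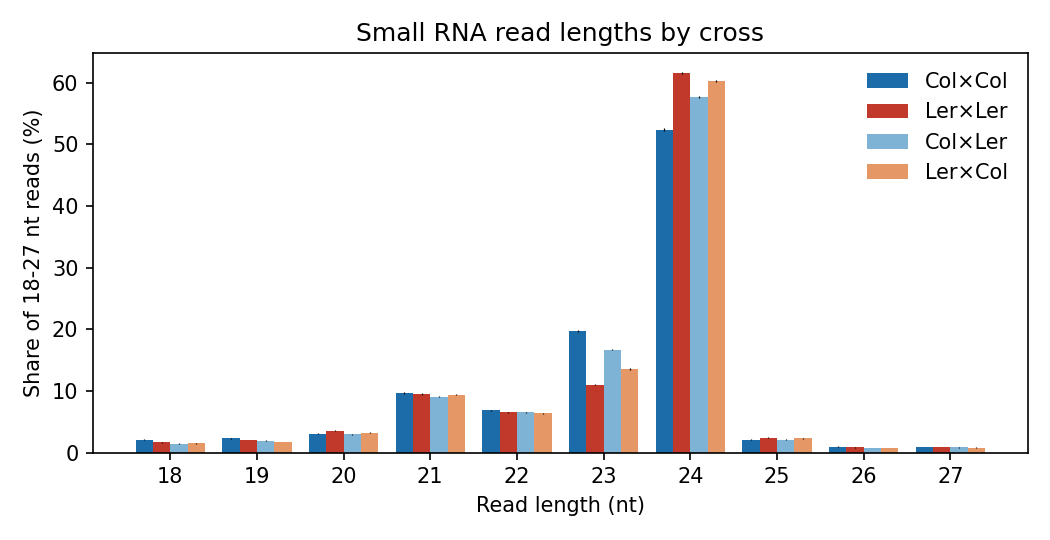
Share of 18 to 27 nt reads at each length (x axis, nt; y axis, percent) in the 4 libraries, drawn as bars from 0 with exact binomial 95% intervals. The 24-nt class is the highest bar in each library, from 52.4% in ColxCol to 61.5% in LerxLer.

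The first question was where in the genome the small RNAs arose. Intergenic sequence was the main class and held 53.4% of matched reads in ColxCol, 53.2% in LerxLer, 58.0% in ColxLer and 50.9% in LerxCol. Protein-coding genes held 14.9%, 22.4%, 15.8% and 20.6% in that order, and pseudogenes, which include many transposon remnants, 7.33%, 8.02%, 8.08% and 8.50%. Transposon sequence outside annotated genes is counted as intergenic, so the pseudogene share is not the share of transposons. All these class shares depend on how many reads matched. Of all reads, matched or not, protein-coding genes held 10.7%, 11.9%, 11.3% and 11.6%, and intergenic sequence 38.1%, 28.2%, 41.4% and 28.6%. The 24-nt reads were concentrated: the 100 fullest of the 500-nt windows held 44.7% of 24-nt reads in ColxCol, 44.3% in LerxLer, 42.2% in ColxLer and 42.3% in LerxCol. Of those windows, ColxCol shared 95 with ColxLer and 68 with LerxLer, while LerxLer shared 94 with LerxCol. The reference is the Col genome, and 71.5% of ColxCol reads but 53.0% of LerxLer reads matched it perfectly, so reads from diverged Ler sequence are counted low throughout.

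Listed miRNAs were more abundant in the libraries whose cross begins with Ler. miR156, the family that holds back the change from juvenile to adult growth by targeting SPL genes, stood at 755 RPM in ColxCol, 3497 in LerxLer, 1671 in ColxLer and 5088 in LerxCol. It was 4.63-fold (3.88 to 5.57) higher in LerxLer than in ColxCol and 3.05-fold (2.75 to 3.37) higher in LerxCol than in ColxLer. Libraries that begin with the same accession differed too. miR156 was 2.21-fold (1.83 to 2.69) higher in ColxLer than in ColxCol and 1.45-fold (1.35 to 1.57) higher in LerxCol than in LerxLer. Of the 8 families with at least 100 reads, 5 were at least 2-fold lower in ColxCol than in LerxLer and 0 were at least 2-fold higher. In the hybrids, 3 of the 8 were at least 2-fold lower in ColxLer than in LerxCol and 0 were at least 2-fold higher. Scaling to matched reads outside structural RNA raised the 3 to 7, and such reads were 62.7% in ColxLer but 48.9% in LerxCol. Shifted miRNA ends, or totals without the most frequent 18S rRNA sequence, each lowered the 3 to 2. Of the 8, miR390 ran the other way. It was 1.78-fold (1.07 to 2.96) higher in ColxLer than in LerxCol and 1.49-fold (0.726 to 3.08) higher in ColxCol than in LerxLer. Listed miRNAs together made up 0.322% of reads in ColxCol, 0.828% in LerxLer, 0.506% in ColxLer and 1.11% in LerxCol.

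Between the selfed libraries the largest ratio among the families with at least 100 reads was that of miR166, which targets the HD-ZIP III genes of organ polarity, at 6.28-fold (3.68 to 11.5) from 15 and 133 reads. miR167, which targets the auxin response factors ARF6 and ARF8, was 3.03-fold (2.22 to 4.19) higher in LerxLer, and miR158 3.12-fold (1.76 to 5.88). miR157, a close relative of miR156, was 2.65-fold (1.72 to 4.22) higher. Between the hybrids, miR158 was 3.56-fold (2.18 to 6.13) and miR159, which targets GAMYB-like genes, 2.02-fold (1.55 to 2.67) higher in LerxCol. miR164, which targets CUC genes at organ boundaries, was 1.66-fold (1.42 to 1.94) higher in LerxLer and 1.78-fold (1.60 to 1.99) higher in LerxCol. In the list of nutrient-responsive miRNAs, 1 of the 7 families went the other way, the copper-responsive miR408, with 17 reads in ColxCol and 0 in LerxLer, at least 7.995-fold higher against a floor of 3 reads. The hybrids had 29 miR408 reads in ColxLer and 2 in LerxCol, a ratio of 25.1 (6.34 to 217). Of the other families in that list, miR827 had 1 read in ColxCol and 4 in LerxLer, miR169 had 1 and 2, and 4 had 0 reads. Beside the miRNAs, 24-nt reads that begin with U, as most of these miRNAs do, were also 1.39-fold (1.32 to 1.46) higher in LerxLer than in ColxCol and 1.57-fold (1.52 to 1.62) higher in LerxCol than in ColxLer.

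**Figure D2:**
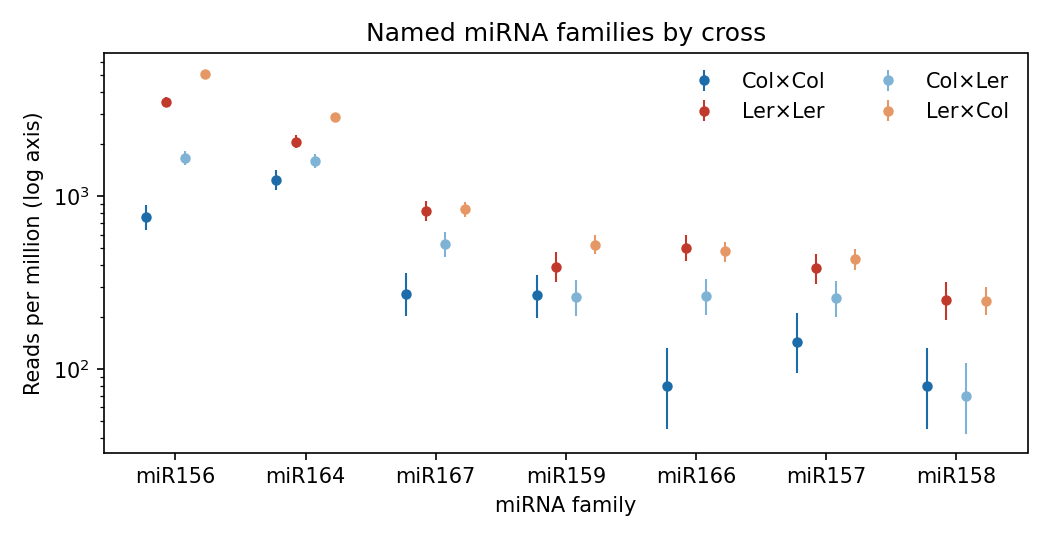
Level in RPM (y axis, log scale) of the 7 miRNA families picked by the naming rule (x axis) in the 4 libraries, with exact Poisson 95% intervals as bars. miR156 runs from 755 RPM in ColxCol to 5088 in LerxCol.

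The selfed crosses were compared to find loci at which the accessions differ in 24-nt siRNA. The highest ratio towards Col was at the pseudogene AT4G07031 (chromosome 4, 4104001 to 4107500, overlapping its exon), with 4454 RPM in ColxCol and 3.79 in LerxLer, from 832 reads and 1 read. That ratio was 1174 (210 to 46420), and 715 (197 to 5909) with 1 mismatch allowed. An intergenic region with no annotated gene within 1000 nt (chromosome 2, 11993001 to 11993500) gave 11345 RPM in ColxCol and 41.7 in LerxLer, a ratio of 272 (152 to 546) that fell to 17.6 (15.2 to 20.5) with 1 mismatch allowed. A region overlapping an exon of CSLD6, a cellulose synthase-like gene (AT1G32180, chromosome 1, 11585501 to 11586500), had 136 reads in ColxCol and 0 in LerxLer, at least 64.0-fold higher. A region overlapping the coding sequence of AT5G40490, a gene for an RNA-binding protein (chromosome 5, 16224501 to 16225500), had 102 and 0 reads, at least 48.0-fold higher.

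Towards Ler, a region overlapping the coding sequence of AT2G06020, a homeodomain-like gene (chromosome 2, 2342001 to 2343000), had 286 reads in LerxLer. ColxCol had 0 reads there, so LerxLer was at least 67.6-fold higher, or 120-fold (33.1 to 999) with 1 mismatch allowed. AT4G04595, annotated as a noncoding RNA (chromosome 4, 1476001 to 1476500), had 230 and 0 reads, at least 54.3-fold higher. The neighbours AT1G20400 and AT1G20405 (chromosome 1, 7076001 to 7078000) stood at 1318 RPM in LerxLer and 16.1 in ColxCol, a ratio of 82.2 (27.9 to 401). A region overlapping the coding sequence of AT3G45840, a gene of the C1 domain family (chromosome 3, 16847501 to 16848000), had 592 RPM in LerxLer. ColxCol had 10.7 there, a ratio of 55.3 (15.1 to 461). Of the 10 named regions higher in ColxCol, 6 overlapped a protein-coding gene, as did 5 of the 10 higher in LerxLer, and all 20 kept at least a 4-fold difference with 1 mismatch allowed.

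By the rule of a 4-fold difference and at least 10 RPM in the higher library, 1831 of 5646 windows were higher in ColxCol and 841 in LerxLer. Counting error alone, drawn from the pooled rates of the 2 libraries, gave 941 and 663 windows on average, because 10 RPM is close to 2 reads in ColxCol. At 50 RPM, a minimum chosen after the data were seen, 239 of 938 windows were higher in ColxCol and 123 in LerxLer, where counting error gave 3.14 and 2.62. With 1 mismatch allowed at that minimum, 254 and 230 of 1280 were. ColxCol held 68.5% of the differing windows, which became 51.6% with scaling to matched reads outside structural RNA, 94.97% with scaling to miRNA reads and 57.2% with 1 mismatch allowed. The median log2 ratio of all windows was 0.53. Scaling to matched and to miRNA reads moved it to -0.35 and 3.23, and totals without the 18S rRNA sequence gave 0.67. With 1 mismatch allowed it was -0.02. The balance of the 2 directions therefore rests on the scaling and on how Ler reads match the Col reference.

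The reciprocal hybrids have the same parents in opposite order, and their libraries were compared to look for differences that go with the direction of the cross. Each of the 20 named regions of the selfed comparison differed between the hybrids in the direction of the accession written first. AT4G07031 stood at 4655 RPM in ColxLer and 2.83 in LerxCol. In whole reads it had 1271 against 1, a ratio of 2196 (393 to 86796). With 1 mismatch allowed it had 1536 against 2, a ratio of 1327 (367 to 10966). Ratios of regions use reads rounded to whole numbers, while levels keep the parts of reads split among several places. The levels of AT4G07031 therefore give smaller ratios than those printed. CSLD6 had 198 reads in ColxLer and 2 in LerxCol, a ratio of 171. AT4G04595 had 286 reads in LerxCol and 0 in ColxLer, at least 55.2-fold higher. AT2G06020 had 439 reads in LerxCol and 1 in ColxLer, a ratio of 254 (45.4 to 10059).

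Ranked by the log2 ratio with its pseudocount, AT4G07031 was first towards ColxLer and AT4G04595 towards LerxCol. A region overlapping the coding sequence of AT1G20030, a thaumatin-like gene of the pathogenesis-related group (chromosome 1, 6947001 to 6948500), had 164 reads in ColxLer. LerxCol had 0 reads there, so ColxLer was at least 94.4-fold higher. With 1 mismatch allowed, LerxCol had 25 reads there and the ratio was 13.7 (9.0006 to 21.7). AT1G20290, annotated as related to a chromatin-binding protein (chromosome 1, 7026001 to 7027000) and also among the regions of the selfed comparison, had 136 and 0 reads, at least 78.3-fold higher. A region at AT5G25400, a nucleotide-sugar transporter gene (chromosome 5, 8824501 to 8826500), had a ratio of 164 (86.2 to 361), but 2.82 (2.55 to 3.12) with 1 mismatch allowed, below the 4-fold rule. Towards LerxCol, AT5G56990, a cystatin-like gene (chromosome 5, 23062001 to 23063500), had 115 and 0 reads, at least 22.2-fold higher.

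In all, 1433 of 5388 windows were higher in ColxLer and 529 in LerxCol, against 314 and 261 from counting error alone. At 50 RPM the counts were 262 and 89 of 1024, against 0.350 and 0.460, and with 1 mismatch allowed 271 and 174 of 1334. ColxLer held 73.0% of the differing windows, which became 60.3% with scaling to matched reads outside structural RNA, 94.1% with scaling to miRNA reads and 62.4% with 1 mismatch allowed. Scaling to matched and to miRNA reads moved the median log2 ratio from 0.49 to -0.23 and 1.89.

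The next comparison asked how far the reciprocal difference follows the difference between the accessions. Across the 5646 windows, the log2 ratio of ColxLer over LerxCol rose with that of ColxCol over LerxLer with a slope of 0.56 (0.54 to 0.58, bootstrap over windows), Pearson's r of 0.690 and Spearman's rho of 0.650. No library enters both axes, and windows are not independent replicates. Counting error in the selfed libraries lowers this slope. Counts drawn from rates pooled over each selfed library and the hybrid that begins with the same accession, a simulation added after the data were seen, gave 0.56 (0.54 to 0.57 over 100 draws). The slope was higher among fuller windows: 0.84 in the 938 windows with at least 50 RPM in a selfed library (r = 0.927), against 0.89 (0.86 to 0.93) in the simulation, and 0.94 in the 154 with at least 500 (r = 0.980), against 0.96 (0.90 to 1.06). Among 3951 windows past 10 RPM in both comparisons, 784 were higher in both libraries that begin with Col, where independent lists would share 251, and 265 in both that begin with Ler, where they would share 52.4. Of the windows called in the selfed comparison, 8 higher in ColxCol and 4 higher in LerxLer were called the opposite way between the hybrids. Among 827 windows past 50 RPM in both, 169 were higher in both libraries that begin with Col, where independent lists would share 44.6. A further 73 were higher in both libraries that begin with Ler, where independent lists would share 9.56, and 0 were called in opposite directions.

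**Figure D3:**
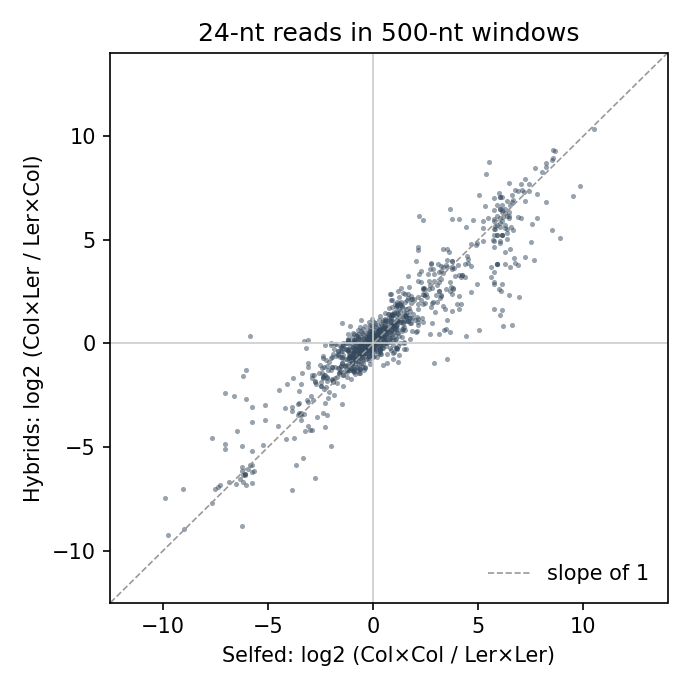
Each point is a 500-nt window with at least 50 RPM 24-nt reads in ColxCol or LerxLer. The x axis is the log2 ratio of the selfed libraries, the y axis that of the reciprocal hybrids, and the dashed line has a slope of 1. The fitted slope is 0.84 over 938 windows, and some windows lie far from the line.

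Sequence differences between the accessions showed which parental genome the reads came from. At 56 positions where ColxCol reads carried the reference base and LerxLer reads another one, 99.89% (99.79 to 99.95) of the 8267 24-nt reads of ColxLer carried the Col allele. In LerxCol, 99.68% (99.55 to 99.78) of 10325 reads carried the Ler allele. The other allele thus made up 0.109% (0.0498 to 0.207) in ColxLer and 0.320% (0.220 to 0.449) in LerxCol. The selfed libraries, which should lack it, had 0.189% (0.0908 to 0.348) in ColxCol and 0.202% (0.104 to 0.352) in LerxLer. In each hybrid the interval overlapped that of the selfed library of its first-written accession. At 192 positions with at least 3 reads, chosen after the data were seen, it did not: the other allele made up 0.410% (0.293 to 0.558) in ColxLer against 0.159% (0.0762 to 0.292) in ColxCol, and 1.26% (1.07 to 1.47) in LerxCol against 0.178% (0.0946 to 0.304) in LerxLer. Those selfed shares are low by construction, since the positions were chosen for purity there, and on sequences held out from the choice ColxLer lay above ColxCol beyond both intervals in 0 of 20 draws and LerxCol above LerxLer in 3. Counted by distinct sequences at the 56 positions, it made up 1.78% in ColxLer, 5.70% in LerxCol, 1.95% in ColxCol and 2.89% in LerxLer. The median over positions was 100% in both hybrids, and 1 position lay under 90% in LerxCol.

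The 21-nt reads gave the same picture at 8 positions, of which 7 lay at or beside a window with a 24-nt position. The first-written accession supplied 99.75% (98.64 to 99.99) of 408 reads in ColxLer and 99.54% (98.68 to 99.91) of 659 in LerxCol. At 11 positions for 23-nt reads the shares were 99.49% and 99.71%. No positions that separate the accessions were found in organelle reads (0 sites), so the seed parent could not be read from them. Siliques hold tissue of the mother plant beside the seeds, and the reads do not separate the sources.

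**Figure D4:**
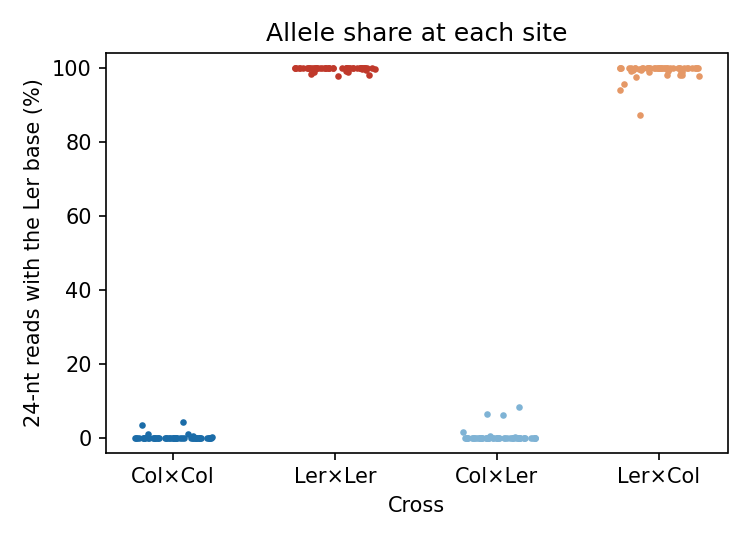
Share of 24-nt reads with the Ler base (y axis, percent) at each of the 56 positions (points, spread sideways for clarity) in the 4 libraries (x axis), with positions without reads left out. ColxLer lies near 0 with ColxCol, and LerxCol near 100 with LerxLer.

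Hybrids were also set against the mean of the selfed libraries. Total 24-nt reads were at a log2 of 0.02 (0.01 to 0.03) in ColxLer and 0.08 (0.07 to 0.09) in LerxCol, and 21-nt reads at -0.08 and -0.03. Reads of all lengths matched outside structural RNA made up 58.1% in ColxCol, 48.0% in LerxLer, 62.7% in ColxLer and 48.9% in LerxCol. Values of matched reads therefore also carry the undercount of Ler reads against the Col reference. The 24-nt reads matched outside structural RNA were at 0.27 (0.26 to 0.28) and -0.10 (-0.11 to -0.08), and the 21-nt reads so matched at 0.09 and -0.20. These signs depend on the scaling: 24-nt reads came to -0.25 in ColxLer with matched reads outside structural RNA, and to -0.06 in ColxLer and -1.12 in LerxCol with miRNA reads, while 21-nt reads in LerxCol came to 0.08 with matched reads. Listed miRNAs were at -0.19 (-0.28 to -0.09) in ColxLer and 0.95 (0.88 to 1.02) in LerxCol, and LerxCol exceeded both selfed libraries. Listed miRNAs starting with U were 1.35-fold (1.28 to 1.42) higher in LerxCol than in LerxLer. Other reads starting with U rose more between these libraries. The 24-nt ones were 1.81-fold (1.75 to 1.87) higher, and the 21-nt ones outside miRNA genes 1.66-fold (1.55 to 1.79). The median window was at -0.11 in ColxLer and -0.43 in LerxCol, at -0.31 and -0.17 with scaling to matched reads outside structural RNA, and at -0.50 and -2.07 with scaling to miRNA reads.

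Among the gene lists fixed before the data were examined, the trans-acting siRNA loci had 4 of 8 members with at least 10 reads in a selfed library. Their median log2 ratio of ColxCol over LerxLer was -0.67, and 1 was at least 2-fold lower and 0 higher. TAS1C (AT2G39675), the largest by reads, stood at 387 RPM in ColxCol, 596 in LerxLer, 521 in ColxLer and 838 in LerxCol. Of 9 measured pentatricopeptide repeat genes, which are known sources of phased siRNA, 3 were at least 2-fold lower in ColxCol and 1 higher. AT1G63070 had 2 reads in ColxCol and 34 in LerxLer, a ratio of 12.05 (3.09 to 103.5) in favour of LerxLer, and AT1G62860 had 13 and 2, a ratio of 9.17 (2.08 to 83.7) in favour of ColxCol. Between the hybrids both kept their direction, with 1 and 65 reads for AT1G63070 and 12 and 3 for AT1G62860.

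Of 5 measured type I MADS-box genes, a family active in endosperm, 2 were at least 2-fold higher and 2 at least 2-fold lower in ColxCol than in LerxLer, while 0 of 6 differed 2-fold between the hybrids. AGL91 (AT3G66656) was the fullest, with 2628 RPM in ColxCol, 5335 in LerxLer, 3946 in ColxLer and 4931 in LerxCol. Of the imprinted genes, 2 of 9 maternally and 2 of 8 paternally expressed members were measured. The maternally expressed AGL36, which is also counted among the type I MADS-box genes above, and MPC were 2.39-fold (1.15 to 5.16) and 2.17-fold (1.03 to 4.75) higher in ColxCol. Between the hybrids MPC went the other way and was 1.71-fold (1.09 to 2.79) higher in LerxCol, from 77 and 26 reads. The paternally expressed YUC10 (AT1G48910), an auxin biosynthesis gene, was 1.99-fold (1.41 to 2.85) higher in LerxLer, with a ratio of 0.997 (0.769 to 1.29) for ColxLer over LerxCol. Against 10000 random lists of like size and abundance, the medians of the 5 lists in both comparisons lay between the percentiles 16.7 and 76.4. With reads that match a single place, the median of the pentatricopeptide repeat list went from -0.54 to -5.28 between the selfed libraries and from -0.58 to -2.50 between the hybrids, and that was not set against random lists.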

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

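The tests on matching, on tissue, on the rest of structural RNA, on scaling and on the first base were chosen only after the results they bear on had been seen. The test of self-fertilised seed, the searches for other forms of the 18S rRNA sequence and the miR156 test per read starting with U were set before their results were seen.

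Hybrid reads carried the allele of the accession written first in the cross. Loss of Ler reads in matching to the Col reference would leave Col reads in excess in both hybrids. The 99.68% share of the Ler allele in LerxCol goes against that at the 56 positions. They were chosen for Ler reads that match with 1 mismatch, so windows and regions that lose Ler reads are not covered. Self-fertilised seed in place of hybrid seed stays open: at positions chosen on a random part of the sequences and read on the rest, the second allele made up 0.0508% (0.00616 to 0.184) in ColxLer against 0.282% (0.113 to 0.580) in ColxCol, and 2.03% (1.60 to 2.54) in LerxCol against 1.55% (1.06 to 2.18) in LerxLer, and over 20 such draws, a repeat added after the first, the medians were 0.881% in LerxCol, 0.686% in LerxLer, 0.291% in ColxLer and 0.285% in ColxCol, and LerxCol lay above LerxLer beyond both intervals in 3 and ColxLer above ColxCol in 0. Seed-parent tissue outweighing the seed cannot be told apart from output of 1 parental genome within the seed, because the 21-nt reads, with a second-allele share of 0.455% in LerxCol, have 1 position away from the 24-nt positions. Uniparental output, the difference that the reciprocal design addresses, remains open and untested against these.

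A 23-nt sequence from the 5' end of the 18S rRNA supplied 7.57% of reads in ColxCol, 0.219% in LerxLer, 4.13% in ColxLer and 2.53% in LerxCol. General breakdown of structural RNA does not account for it, since the rest of structural RNA was only 1.20-fold (1.17 to 1.24) higher in ColxCol than in LerxLer, against 34.5-fold for the sequence. A Ler variant or another length is argued against too, as sequences 1 mismatch away made up 0.0322% of LerxLer reads and other lengths from the same 5' end 0.0205%. An effect of single libraries or of the accessions remains open, with 1 library per cross.

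Listed miRNAs were higher in LerxLer and LerxCol. The 18S rRNA sequence in the totals is not the reason, since miR156 was still 4.29-fold higher in LerxLer than in ColxCol without it. Capture that depends on the first base of the RNA is a candidate explanation for part of the pattern: 24-nt reads starting with U were 1.39-fold higher in LerxLer, and listed miRNAs starting with another base were not higher (0.448-fold, 0.276 to 0.717, from 31 and 49 reads, and 0.687-fold, 0.405 to 1.16, without miR408, left out after its values were seen). It is argued against as the whole cause for miR156, which stayed 3.76-fold (3.07 to 4.62) higher per 21-nt read starting with U outside miRNA genes, while LerxCol over ColxLer fell from 3.05 to 1.94 (1.72 to 2.19). These values overstate what is left, since those 21-nt reads had to match the Col genome perfectly, which loses Ler reads. The 21-nt reads starting with A, counted likewise, were at 0.783 (0.756 to 0.810) in LerxLer over ColxCol and 0.726 (0.705 to 0.747) in LerxCol over ColxLer. miR156 also has another length than these reads. A difference between the accessions remains open and untested.

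Some shares of all kept reads, matched or not, moved in opposite directions from a selfed library to the hybrid that begins with the same accession. That difference was not tested across replicates. Structural RNA was at 0.642 of its ColxCol share in ColxLer and at 1.56 of its LerxLer share in LerxCol, and 23-nt reads were at 0.848 and 1.23. Reads of 24 nt were at 1.10 and 0.980, and protein-coding gene reads at 1.06 and 0.973. These 4 were found among 26 classes, lengths and families compared. With the 18S rRNA sequence left out of reads and totals, a step added after the moves were seen, none of the 4 was opposite beyond the intervals: structural RNA came to 0.774 (0.752 to 0.797) and 1.01 (0.984 to 1.03), and 24-nt reads to 1.06 (1.05 to 1.07) and 1.003 (0.997 to 1.01). Reads of 23 nt came to 0.9999 (0.983 to 1.02) and 1.05 (1.03 to 1.06), and protein-coding gene reads to 1.02 (1.001 to 1.04) and 0.996 (0.982 to 1.01). The most frequent sequence without a genome match, of 21 nt and outside the comparisons above, made up 0.361% of reads in ColxCol, 0.472% in LerxLer, 0.640% in ColxLer and 0.895% in LerxCol, above the limit that a count of 0 allows.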

How the results depend on the processing

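No paired analysis was possible because each cross has 1 library and the labels carry no replicate numbers. The minimum of 50 RPM, the totals without the 18S rRNA sequence, the 20 to 25 nt reads, the 8-fold rule, the positions with at least 3 reads and the 18 to 27 nt allele reads were chosen after seeing the data; unless a reason is given, the cause was not tested. The 24-nt share became 51.7%, 55.2%, 54.3% and 55.6% (ColxCol, LerxLer, ColxLer, LerxCol) with distinct sequences and 66.1%, 67.3%, 67.9% and 67.7% among perfect matches outside structural RNA. The intergenic share became 64.9%, 57.7%, 66.0% and 57.9% with single matches, and 55.9% in LerxLer and 54.0% in LerxCol with 1 mismatch. Families at least 2-fold lower in ColxLer than in LerxCol, 3 as reported, numbered 7 with scaling to matched reads outside structural RNA. They numbered 2 with shifted miRNA ends and 2 with totals without the 18S rRNA sequence. The count of windows higher in ColxCol, 1831, became 1073 with that scaling, 7001 with miRNA scaling, 709 at 20 RPM, 837 with a pseudocount of 5 and 239 at 50 RPM. The 841 higher in LerxLer became 371 with miRNA scaling, 1405 with 1 mismatch, 342 at 20 RPM, 416 with a pseudocount of 5 and 123 at 50 RPM. The 1433 higher in ColxLer became 2414 with miRNA scaling, 672 at 20 RPM, 624 with a pseudocount of 5 and 262 at 50 RPM. The 529 higher in LerxCol became 150 with miRNA scaling, 835 with 1 mismatch, 226 at 20 RPM, 217 with a pseudocount of 5 and 89 at 50 RPM. Stricter minimums lower each count by construction. Totals without the 18S rRNA sequence, 1000-nt windows, single matches, 20 to 25 nt reads and the 8-fold rule left all 4 counts within 1.5 times of those reported. The slope became 0.54 with single matches, 0.72 at 20 RPM and 0.64 with a pseudocount of 5. The first accession's share of 24-nt alleles became 98.2% in ColxLer and 94.3% in LerxCol with distinct sequences, where the selfed libraries had 98.0% and 97.1%, then 99.59% and 98.74% with positions of at least 3 reads, and 99.39% and 99.14% with 18 to 27 nt reads. For 21-nt alleles, distinct sequences gave 98.2% and 93.3%, from 57 and 45 sequences. Against the mean of the selfed libraries, scaling to matched reads outside structural RNA gave miRNAs -0.50 in ColxLer, 24-nt reads -0.25 in ColxLer, a changed sign, and 0.18 in LerxCol, 21-nt reads -0.33 in ColxLer and 0.0795 in LerxCol, a changed sign, and the median window -0.31 and -0.17. Scaling to miRNA reads gave 24-nt reads -0.057 in ColxLer and -1.12 in LerxCol, both changed signs, 21-nt reads -0.20 and -1.29, and the median window -0.50 and -2.07. With single matches the pentatricopeptide repeat list moved from -0.54 to -5.28 in the selfed and from -0.58 to -2.50 in the hybrid comparison. The maternally expressed list moved to 1.20 without flanks and 1.39 with single matches in the selfed comparison, and the paternally expressed list to -0.11 and -0.0538 in the hybrid comparison, each resting on 2 genes. Leaving the 18S rRNA sequence out of reads and totals, added after seeing the data, gave 24-nt reads a log2 ratio of LerxCol over LerxLer of 0.0043, a changed sign. Of 224 values of single miRNAs, regions and read classes under alternatives, 152 stayed within their counting interval, 71 moved and 1 changed sign. Depth limits the low windows most: in ColxCol, 3 reads equal 16.1 RPM, above the minimum of 10.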

Other observations

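Windows with 24-nt reads were compared with the genome as a whole, after their number was known. Windows that touch a protein-coding gene made up 61.9% of the genome's windows but 22.02% of those past 10 RPM in a selfed library, and windows that touch only a pseudogene made up 10.4% and 17.2%. Among the windows that differed, 23.2% of those higher in ColxCol and 26.2% of those higher in LerxLer touched a protein-coding gene. Counting error alone gave 941 and 663 such windows on average, against 1831 and 841 called. In the hybrids it gave 314 and 261, against 1433 and 529 called. The make-up of differing windows given here may therefore owe much to counting error. Regions with less than 131.5 protein-coding genes per megabase, which lie largely around the centromeres, covered 16.0% of the genome's windows and 26.2% of those past 10 RPM in a selfed library, against 23.3% of those higher in ColxCol and 30.7% of those higher in LerxLer. In the hybrids they covered 27.3% of windows past 10 RPM, 17.4% of those higher in ColxLer and 32.5% of those higher in LerxCol. They held 22.9% (22.6 to 23.2) of 24-nt reads in ColxCol, 20.3% (20.1 to 20.6) in LerxLer, 23.4% in ColxLer and 23.2% in LerxCol. Reads of 21 nt from TAS genes stood at 567 RPM in ColxCol, 935 in LerxLer, 707 in ColxLer and 1014 in LerxCol.

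Positions with few reads gave another allele picture than the 56 well covered ones. At 136 positions with at least 3 reads but short of the main minimum, the second allele made up 2.03% (1.38 to 2.86) in ColxLer and 5.75% (4.80 to 6.82) in LerxCol, against 0% and 0.0730% in the selfed libraries of the same first accession. Those selfed values are low by construction, since the positions were chosen for being pure there. When positions were chosen on a random part of the sequences and read on the rest, the low-covered ones gave 6.50% (4.36 to 9.25) in LerxLer itself and 9.28% (7.28 to 11.6) in LerxCol, with overlapping intervals, and 0.108% (0.00274 to 0.602) in ColxLer. Those are values of 1 draw, in which 27 of the 32 second-allele reads of LerxLer and 62 of the 74 of LerxCol came from 11 positions in gene-poor regions. Over all positions LerxLer had 1.55% and LerxCol 2.03% in that draw, both near the top of the 20 draws (0.0668% to 1.69%, median 0.686%, and 0.339% to 2.66%, median 0.881%), so how much of the second allele in LerxCol selfed Ler also holds stays open. A position on chromosome 4 (2073770, intergenic, no annotated gene within 1000 nt), chosen after its values were seen, had 17 of 35 reads with the Col base in LerxCol and 0 of 18 in LerxLer. It was the 1 position among 134 tested in LerxCol whose interval lay above that of LerxLer. It was not alone in a high share: 11 positions had at least 25% second allele in a hybrid, 8 of them in gene-poor regions. At another of these (chromosome 3, 12134924), 16 of 19 LerxCol reads had the Col base, but LerxLer had only 3 reads. With so few selfed reads the interval rule can hardly be met.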
